A study of Mus musculus with 9 samples.

How the data were processed

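Single-cell RNA sequencing libraries had been made from mouse embryonic stem cells on 8 days of a culture series, with droplet-based kits of 10x Genomics on cells purified by FACS, per the labels' protocols. In this assay each cell is captured in a droplet with a bead, and the bead gives all transcripts of that cell 1 barcode. The gate used for sorting, the filters on cells and the handling of doublets are not given in the sources used here. Cell Ranger 3.1.0, Seurat 3.2.3 and the mouse genome build mm10 are named in the submitters' processing notes, with no role or order.

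The deposited table analysed here held 1 row per listed cell, with a barcode of 16 bases followed by a library number, and the name of the library. Both columns were text, and per the file headers they were a barcode and a sample name, so no expression value, UMI count, detected-gene number, mitochondrial share, cluster, cell class or cell cycle phase entered the results. The ninth sample of the series, cells of mouse blastoids, had no row in this table and was not analysed here. Gene-level and class-level results fixed before the data were examined (shares of 2-cell-like and trophoblast classes, depth per cell, phase shares and marker genes) were therefore not computed, and all 40 alternatives listed for them were not run. The rule for named genes gave no gene a value. A gene annotation was at hand and was not used here.

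Each library name was matched to a sample by the day in that sample's title. All 8 names matched, and 0 rows were left unmatched. Every library name went with 1 library number. Cells were counted per library, and the share of all listed cells was computed for each. Intervals are exact 95% intervals, Poisson for numbers and Clopper-Pearson for shares. They are two-sided and cover counting error only. For a count of 0 the limit given is one-sided, 3 cells of a library, which is lower than the upper end of the two-sided interval. Each day had 1 library, so there was no replicate of any day, no test of one day against another was made, and no p-value was computed from cells. A trend of cell number with day over the 8 libraries was tested by exact permutation.

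Barcodes were then compared between libraries, a comparison chosen after the data were seen. A barcode was called shared when its 16 bases were identical in both libraries. Beads are drawn from a finite set of barcodes, so unrelated libraries share some by chance. The size of that set was estimated from the 10 pairs among the 5 libraries of days -2, 0, 1, 2 and 4, as the sum of the products of their cell numbers divided by the sum of their shared barcodes. The chance value of a pair is the product of its cell numbers divided by this size. Intervals of ratios to chance hold this value fixed, so they leave out the error of its estimate. The calculation was tested on simulated data of the real library sizes, drawn from equally likely barcodes, as the calculation assumes. Such data cannot show how it behaves with uneven barcode frequencies. The 1000 simulated pairs in the results were also drawn from equally likely barcodes. In 20 runs with 400 barcodes planted in the pair of days 6 and 8, the recovered excess in that pair was 397.6 ± 3.7 (SD over runs), and the highest ratio to chance in any pair with no planted barcodes was 1.75. Alternatives left out barcodes listed in several libraries, or estimated the set from other, overlapping selections of pairs of libraries. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and plots used Matplotlib 3.10.9.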

Results

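The series followed mouse embryonic stem cells (ESCs), the pluripotent cells of the early embryo kept in culture, under sodium butyrate, an inhibitor of histone deacetylases. By its title, the series asked whether changing histone deacetylase activity turns ESCs into trophoblast stem cells (TSCs), the stem cells of the placental lineage. Untreated ESCs were sampled on day -2. Cells sampled on day 0 had been kept for 2 days in ESC medium with sodium butyrate at 0.5 mM. Cells of days 1, 2, 4, 6, 8 and 10 had then spent that many days in TSC medium, with sodium butyrate still present and on a layer of irradiated mouse embryonic fibroblasts. Each of these 8 days was represented by 1 single-cell library. The values below are numbers of cells and of cell barcodes, and gene expression and cell classes were not analysed here.

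The table listed 78424 cells over the 8 libraries, with a median of 10017.5 cells per library. Untreated ESCs of day -2 contributed 10101 cells, or 12.9% of the total (exact 95% interval 12.6 to 13.1%). The 7 libraries exposed to sodium butyrate contributed the other 68323 cells, or 87.1%, a share set largely by their being 7 of the 8 libraries. After 2 days of sodium butyrate in ESC medium, 12816 cells were listed, 1.27 times the number on day -2. In TSC medium, 9934 cells were listed on day 1 and 8149 on day 2. The library of day 4 was the largest of the series with 13772 cells, or 17.6% of the total (17.3 to 17.8%). The library of day 6 was the smallest with 4464 cells, or 5.69% (5.53 to 5.86%). Numbers were 10317 on day 8 and 8871 on day 10.

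Between the largest and the smallest library the number of listed cells differed 3.09-fold. The library of day 6 held 0.442 times as many cells as that of day -2, whereas the other 7 libraries lay between 8149 and 13772 cells. The exact Poisson interval for day 6 was 4334 to 4597 cells and that for day 2, the next smallest library, was 7973 to 8328 cells, so the gap was larger than counting error. The spread between libraries of the same day is unknown, since no day had a replicate. Counts of listed cells depend on how many cells were loaded and on the filters applied before deposit, and they do not measure cell number in culture.

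**Figure D1:**
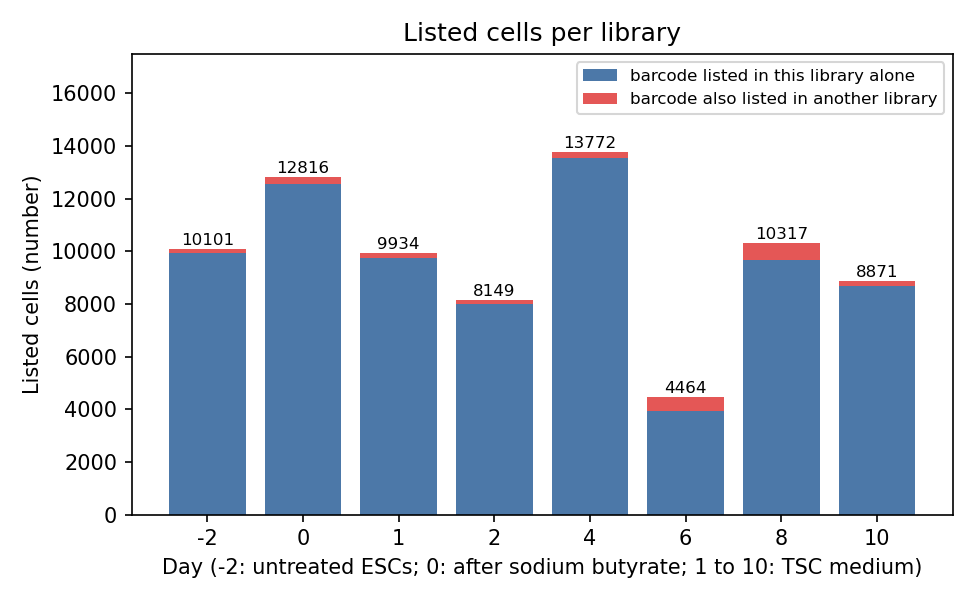
Number of listed cells (y axis) in the single library of each day (x axis), with the total above each bar. The lower part of a bar counts cells whose barcode was listed in that library alone, and the upper part counts cells whose barcode was also listed for another day, which were 526 of 4464 cells on day 6 and 657 of 10317 cells on day 8.

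These numbers limit the precision that any rare population can have in each library. A population of which no cell was seen could still make up 0.0672% of the cells of day 6, 0.0297% of those of day -2 and 0.0218% of those of day 4, by the one-sided limit of 3 counts and for counting error only.

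The cell barcodes were compared between libraries to see whether the 8 lists were independent of each other. No barcode was listed more than once within a library. Across libraries the 78424 cells carried 77237 different barcodes, of which 76067 were listed in 1 library, 1153 in 2 libraries and 17 in 3 libraries. The 10 pairs among days -2, 0, 1, 2 and 4 shared 333 barcodes, which corresponded to drawing from 3571972 equally likely barcodes (exact Poisson 95% interval 3208209 to 3988951). Ratios of observed to chance sharing among these 10 pairs ran from 0.847 to 1.15.

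The libraries of days 6 and 8, both in TSC medium, shared 455 barcodes, against 12.9 given by chance. The ratio was 35.3 (32.1 to 38.7), and the highest number in 1000 simulated pairs of the same sizes was 29. The shared barcodes made up 10.2% of the cells of day 6 (9.32 to 11.1%) and 4.41% of the cells of day 8 (4.02 to 4.82%). The libraries of days 8 and 10 shared 58 barcodes, against 25.6 given by chance, a ratio of 2.26 (1.72 to 2.93), and the highest number in 1000 simulated pairs was 44. Days 6 and 10 shared 13 barcodes, against 11.1 given by chance. Apart from the pairs of days 6 and 8 and of days 8 and 10, the intervals of all 26 pairs held the chance value, with ratios between 0.811 and 1.25. The 26 pairs include the 10 that gave the chance value, so the ratios of those 10 are no independent check. The 7 pairs that included the untreated ESCs of day -2 had ratios between 0.837 and 1.10. Of these 7, the pairs with days 0, 1, 2 and 4 are among those 10.

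**Figure D2:**
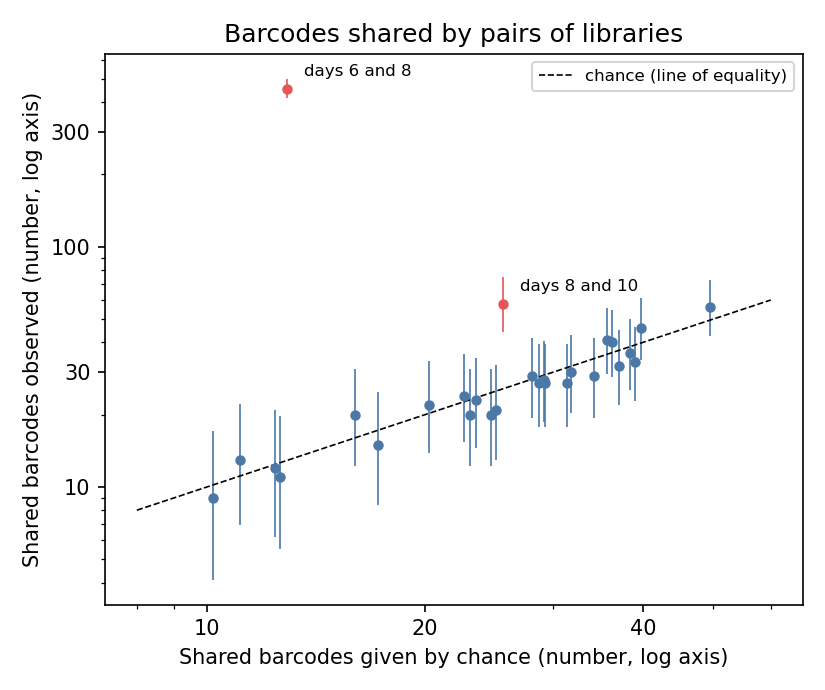
Barcodes shared by each of the 28 pairs of libraries (y axis, log scale) against the number given by chance (x axis, log scale). Points are pairs, bars are exact Poisson 95% intervals and the dashed line marks equality; the pair of days 6 and 8 lies at 455 against 12.9, and the pair of days 8 and 10 at 58 against 25.6.

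Counted by library, 11.8% of the cells of day 6 (10.9 to 12.8%) and 6.37% of the cells of day 8 (5.90 to 6.86%) carried a barcode that was also listed for another day. Chance gives 2.05% for day 6 and 1.89% for day 8. For untreated ESCs of day -2 the share was 1.76% (1.51 to 2.04%), with 1.90% given by chance. For cells of day 0 it was 1.89% (1.66 to 2.14%), with 1.82% given by chance. For day 10 it was 2.07% (1.79 to 2.39%), with 1.93% given by chance.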

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

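The tests in this part were all chosen after the barcodes had been compared. Barcode sharing lies outside the counts of cells that the design called for, and 2 pairs of libraries had a sharing ratio whose lower bound exceeded the highest upper bound of any pair with untreated ESCs (1.56). These were days 6 and 8, with 455 shared barcodes, and days 8 and 10, with 58. The second flag depends on taking the pairs of day -2 as the bar. Its lower bound (1.72) lay below the upper bounds of days 0 and 6 (1.93) and of days 6 and 10 (2.01).

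Barcodes that days 6 and 8 had in common were not barcodes that are frequent everywhere. Of these 455 barcodes, 1.76% were also listed for at least 1 other day (exact 95% interval 0.762 to 3.43%), and of the other 4009 barcodes of day 6, 1.77% were listed for a day other than 8 (1.39 to 2.23%). Uneven barcode frequencies common to the beads of all libraries would have raised the first share, so they are argued against as the cause. The shares cannot address unevenness confined to the beads of days 6 and 8, which would leave other days unchanged. A single library listed under both days is argued against as well, since only 10.2% of the barcodes of day 6 were listed for day 8. Barcoded molecules or reads crossing from day 8 into other libraries remain open. In all, 4 barcodes were listed for days 6, 8 and 10 (exact Poisson interval 1.09 to 10.2), against 2.56 if sharing with each were independent. This count cannot decide the question, since crossing that struck unrelated barcodes of day 8 in each library would also give the independent number. The direction of any crossing was not tested. A barcode comes from the bead and not from the cell, so no biological explanation was tested.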

How the results depend on the processing

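All alternatives run here were chosen after seeing the data, and those fixed before the data were examined needed per-cell values not analysed here. Counting cells whose barcode was listed in 1 library alone moved the number outside its counting interval for day 0 (12574 cells), day 4 (13535), day 6 (3938), day 8 (9660) and day 10 (8687), and kept it inside for days -2, 1 and 2. Leaving out only the barcodes that days 6 and 8 share gave 4009 cells for day 6 and 9862 for day 8. These settings drop cells by construction, and the number for day 10 lay at the edge of its interval. Only on days 6 and 8 was the share with a barcode in another library above chance beyond its interval. Day 6 stayed the smallest library under each setting. This is no check of its rank, since these settings took the largest share of cells from day 6. The chance value was also estimated from other selections of pairs, or without each of the 5 libraries behind it. The ratio then ran from 34.0 to 38.1 for days 6 and 8 and from 2.18 to 2.44 for days 8 and 10. All lay within the counting interval of the reported values. These selections shared pairs with the reported estimate, so they are no independent check. The selection of all pairs except days 6 and 8 also included the pair of days 8 and 10 itself. No paired analysis was possible because each day had 1 library. Depth in reads or UMIs was not analysed here, so how firmly each listed barcode stands for a cell is unknown.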

Other observations

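The relation of cell number to day was tested after the counts had been seen. One hypothesis was that fewer cells were listed on later days. Over the 8 libraries Spearman's rho between the day and the number of listed cells was -0.26 (exact two-sided permutation test, p = 0.536) and Pearson's r was -0.30 (exact permutation p = 0.48). Cell number against day was the only relation computed, by both measures and also in the subsets below, and the p-values were not adjusted. Without days 8 and 10, Pearson's r was -0.43, and without days -2 and 10, which lie as far from the median day, it was -0.34. With 8 libraries no trend was detectable, and a trend is not excluded.

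In all 78424 listed cells the ninth base of the barcode was fixed by the eighth, so that each base at the first of these positions was followed by a single base at the other. This held in every one of the 8 libraries.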
